A study of Mus musculus with 6 samples.

How the data were processed

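The samples were 6 RNA-seq libraries of MC38, a mouse colorectal cancer cell line, 3 from cells with a control short hairpin RNA (shControl) and 3 from cells with a short hairpin RNA against Acsl4 (shACSL4). Total RNA was depleted of ribosomal RNA, fragmented and primed with random hexamers. Per the submitters' processing notes, the reads were handled with CASAVA, HISAT2 and DESeq2 against the GRCm39 build. The program that counted reads, the annotation release, the versions and the strandedness of the libraries were not given in the sources used here, so the treatment of reads shared by near-identical genes is unknown.

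The deposited table held raw counts per gene for each library, per the file headers and as checked on the values, which were whole numbers. It also held FPKM values that the authors made from those counts, with a gene length whose definition was not given. The log2 fold change of shACSL4 over shControl and its p-value in the deposited table were computed by the authors, with DESeq2 named in their notes. The table listed 22386 genes with identifiers, symbols, GRCm39 coordinates, biotypes, and GO and KEGG terms. Every per-sample column was used, the counts for all tests and the FPKM values for Acsl4.

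The total count per library was 41813345, 40911698 and 42058293 in shControl 1 to 3, and 41134232, 42950108 and 47127672 in shACSL4 1 to 3. A count of 0 in a library allowed up to 3 counts, or 0.0637 to 0.0733 counts-per-million (CPM). This floor covers counting error only.

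Counts were analysed in R 4.3.3. The main test was edgeR 4.0.16's robust quasi-likelihood test, two-sided, with group as the only term, TMM scaling and edgeR's expression filter at a minimum count of 10 and a minimum total of 15. P-values were adjusted by the Benjamini-Hochberg method over the 14289 genes left, with a threshold of 0.05. Adjusted p-values of genes come from this test unless another tool is named. Standard errors of log2 fold changes were the fold change divided by the square root of the test's F statistic. Group levels are means ± SD over 3 libraries in TMM-scaled CPM.

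The 34 gene lists covered fatty acid activation, ferroptosis, lipid metabolism, interferon and antigen presentation, immune regulators, cytokines, cell cycle, stress responses, mitochondria, ribosomes, matrix, lysosome and histones. They also held markers of colorectal epithelium and of other cell types. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1), two-sided, at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Members were also counted as adjusted over the list alone. GO and KEGG terms of 10 to 300 tested genes were tested with Fisher's exact test, two-sided, against tested genes that carry a term, with Benjamini-Hochberg adjustment over terms and both directions. Cells of 2601 genes in the GO column and 19 genes in the KEGG column had been blanked out and were left out.

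The genes to name were set by rule. They were Acsl4 and the 10 largest rises and 10 largest falls among changed genes with a mean of at least 5 CPM, no overlap between groups and an established symbol. Up to 4 members with the smallest adjusted p were taken from each list. The other long-chain acyl-CoA synthetases and Gpx4, Slc7a11, Lpcat3, Ptgs2, Cd274, B2m, H2-K1, H2-D1, Cxcl10, Ccl5 and Ccl2 were named whatever their result. A few genes that the rule takes are not reported here. The comparison, tests, lists, naming rule and most alternatives were chosen before the data were examined.

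The alternatives were DESeq2's size factors or library size alone as scaling, DESeq2 1.42.0 and limma-voom as tests, no filter, a stricter filter (1 CPM in 3 libraries and a total of 60 counts), protein-coding genes alone, the replicate number as a block, a fold change threshold of 1 on the log2 scale, and each library left out in turn. All other splits of the 6 libraries into 3 and 3 were also fitted. The supplied reference annotation was on another build, so it gave transcript lengths by gene identifier only. The workflow was tested on simulated data with the same library sizes. There edgeR recovered 76.6% of genes changed 1.5-fold, 78.5% at 2-fold and 98.5% at 4-fold, and 8.38% of its calls were false. That false share lies above the adjusted p threshold of 0.05. Only 64 or 65 of the 14038 simulated genes tested were changed at each fold, whereas 29.1% of tested genes changed in the real data. Whether the recovery and the false share carry over to the real data was therefore not tested.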

Results

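RNA-seq counts were compared between MC38 cells with a control short hairpin RNA (shControl, 3 libraries) and MC38 cells with a short hairpin RNA against Acsl4 (shACSL4, 3 libraries). MC38 is a mouse colorectal cancer cell line, and Acsl4 encodes an enzyme that activates arachidonate and other long polyunsaturated fatty acids with coenzyme A. The comparison asks what reduced Acsl4 does to the transcriptome of these tumour cells, in a series concerned with immune suppression in colorectal cancer. The series describes the cells as knockouts, whereas the sample names give short hairpin RNAs. Library totals were 41813345, 40911698 and 42058293 counts in shControl 1, 2 and 3, and 41134232, 42950108 and 47127672 in shACSL4 1, 2 and 3. Levels are given in TMM-scaled counts-per-million (CPM). Nothing states that replicates of a group were separate cultures, so every p-value measures only the spread between these libraries.

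Acsl4 was lower in every shACSL4 library than in every control, and the prostaglandin synthase gene Ptgs2 fell. All 43 tested interferon-stimulated genes and 19 of 23 genes of MHC class I presentation rose, and camera's test of each list gave adjusted p = 0.292 with an estimated correlation. Acsl4 (ENSMUSG00000031278, GRCm39 chromosome X, 141100989 to 141173531) was at 191.1, 194.2 and 203.6 CPM in shControl 1 to 3 and at 131.7, 127.7 and 126.7 CPM in shACSL4 1 to 3. Its mean went from 196 ± 6.53 to 129 ± 2.67 CPM (SD, n = 3), a fall to 0.656 of the control level (log2 fold change -0.61, SE 0.0517, adjusted p = 3.84e-06). In the authors' FPKM values it went from 36.2 ± 0.733 to 23.9 ± 0.567. Cd274, which encodes the checkpoint ligand PD-L1, rose 2.95-fold, from 8.48 ± 1.27 to 25 ± 3.67 CPM (adjusted p = 4.04e-06).

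**Figure D1:**
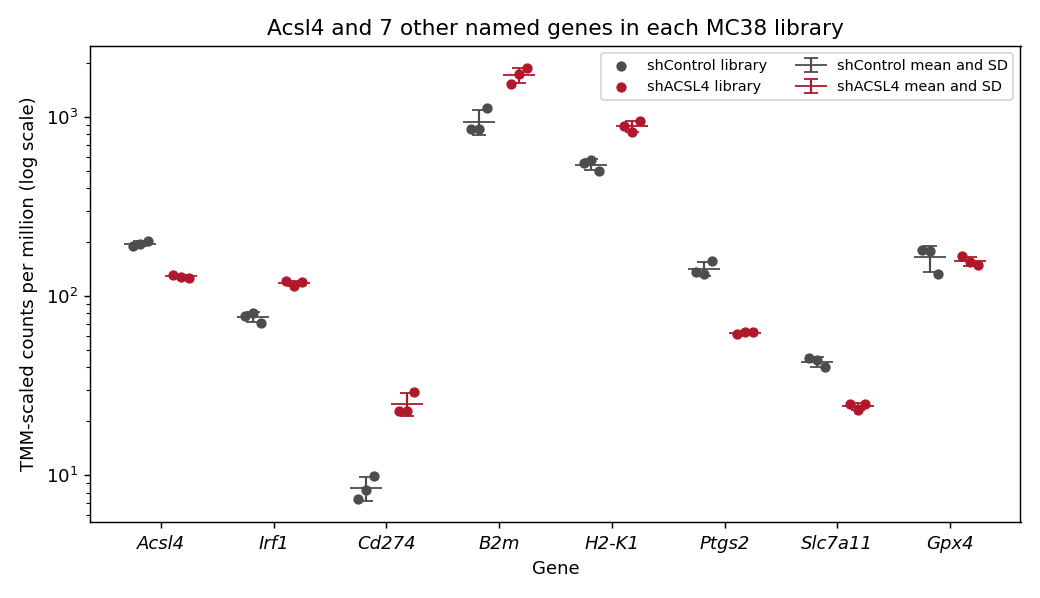
Expression of 8 genes in each library, as TMM-scaled CPM on a log axis; points are libraries, bars are group means and whiskers are SD over 3 libraries. Acsl4, Ptgs2 and Slc7a11 were lower in all 3 shACSL4 libraries than in all 3 controls, Irf1, Cd274, B2m and H2-K1 were higher, and Gpx4 overlapped (164 against 157 CPM).

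Of 14289 genes tested, 4155 (29.1%) changed, 2205 higher and 1950 lower in shACSL4. Changes of at least 1 on the log2 scale were found for 706 higher and 133 lower genes. The groups did not overlap for 6122 genes (42.8%), where chance gives 10%. Tenm2, which encodes a teneurin (chromosome 11, 35897483 to 37126791), rose from 0.331 ± 0.0877 to 13 ± 0.895 CPM (log2 fold change 5.29, SE 0.187, adjusted p = 2.36e-09). Stra6, which encodes a receptor for retinol-binding protein, rose from 0.361 ± 0.157 to 9.77 ± 0.299 CPM (4.74, SE 0.225, adjusted p = 2.52e-08). The other 8 largest rises were the interferon-inducible genes Ifi207, Iigp1, Zbp1, Oas2, Tgtp1, Ifit3b, Ifit3 and Ifi44, with log2 fold changes of 4.41 to 5.23 and adjusted p of 0.0013 to 0.0117. Zbp1, a sensor of Z-form nucleic acids, rose from 1.03 ± 0.0459 to 37 ± 19 CPM, and Ifi44 from 6.12 ± 2.39 to 130 ± 63.3 CPM. Mmp12, a matrix metalloelastase gene, fell by 2.32 on the log2 scale (SE 0.183, adjusted p = 4.75e-06), from 18 ± 0.8 to 3.62 ± 1.09 CPM. Inhba, which encodes the activin A subunit, fell by 1.72 (SE 0.0732, adjusted p = 9.07e-09), from 224 ± 8.51 to 67.8 ± 7.26 CPM. The remaining large falls were in Slc4a4, Col7a1, Nptx1, Rbpms2, Has2, Pdlim1, Lbh and Mid2, with log2 fold changes of -1.90 to -1.39 and adjusted p of 7.31e-08 to 2.98e-05. Left-out libraries ended the calls of Ifit3 (adjusted p = 0.0604 without shControl 1, 0.0551 without shControl 2) and Ifit3b (0.0613 and 0.0549), and the number of lower genes was 1252 without shACSL4 3. limma-voom ended those of Ifi207 (adjusted p = 0.0531), Iigp1 (0.0517) and Ifit3b (0.0747), and near-identical copies of Ifit3, Iigp1 and Tgtp1 leave the split of their reads uncertain.

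**Figure D2:**
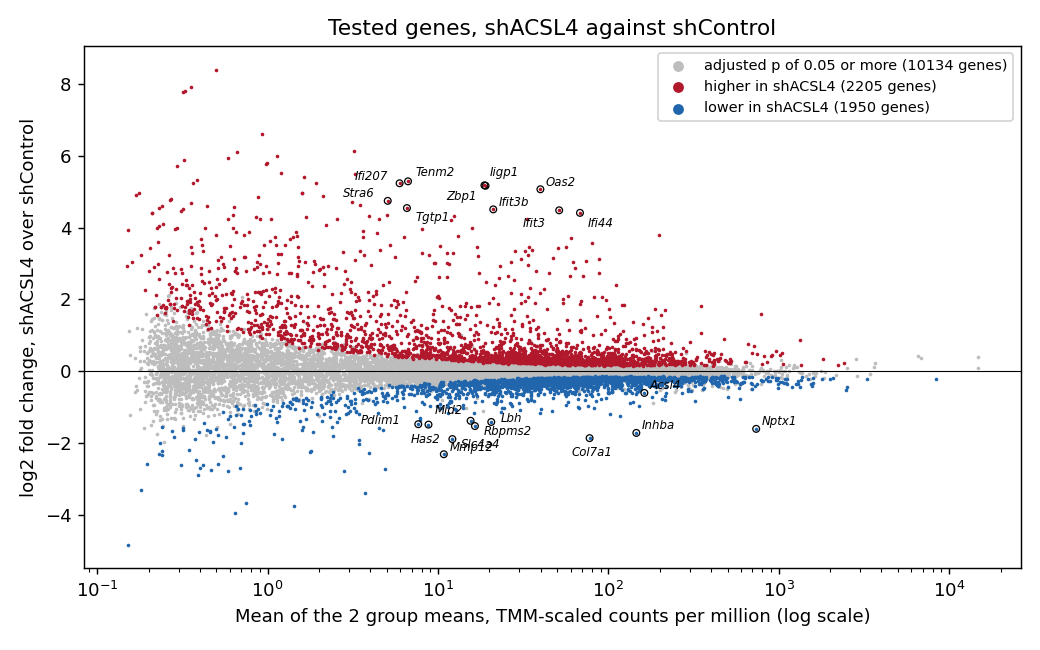
Each of the 14289 tested genes as a point, with the mean of both group means in TMM-scaled CPM (log axis) against the log2 fold change of shACSL4 over shControl. Colours mark adjusted p under 0.05, and circles mark Acsl4 and the 10 largest rises and 10 largest falls that were named. Large changes were mostly rises, 706 of the 839 of at least 1 on the log2 scale.

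Interferon-stimulated genes rose as a group: all 43 tested members were higher (43 adjusted over the list alone), with a median log2 fold change of 3.04. Camera's adjusted p was 1.14e-53, and adjusted p = 0.292 with an estimated correlation (unadjusted p = 0.0353), while fry gave adjusted p = 0.00487. The adjustment gives 0.292 to several lists whose unadjusted p differed. With an estimated correlation the unadjusted camera p was 0.0238 for MHC class I and 0.0821 for fatty acid synthesis. Ifi27 rose by 1.54 (SE 0.083, adjusted p = 7.31e-08), Irf1 by 0.63 (SE 0.0606, adjusted p = 1.02e-05) and the RNA helicase gene Dhx58 by 3.00 (SE 0.225, adjusted p = 1.1e-05). MHC class I processing and presentation had 19 of 23 members higher and 0 lower at adjusted p under 0.05 (19 and 0 adjusted over the list alone), with a median of 0.86 and camera adjusted p = 1.3e-22 (adjusted p = 0.292 with an estimated correlation). B2m, the light chain of class I molecules, rose from 943 ± 154 to 1713 ± 174 CPM (adjusted p = 0.00106), and the heavy chain genes H2-K1 and H2-D1 rose 1.64-fold and 1.68-fold (adjusted p = 1.05e-05 and 6.16e-06). Tapbp, which encodes the loading chaperone tapasin, rose 2.36-fold, H2-Q4 2.02-fold, H2-T23 5.24-fold and the peptide transporter gene Tap2 1.82-fold, with adjusted p of 1.69e-07 to 4.64e-06. The H2 genes resemble each other closely, so the share of reads each received is uncertain.

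Nucleic acid sensing had 13 of 20 members higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 0.74 and camera adjusted p = 8.51e-07 (adjusted p = 0.292 with an estimated correlation). Of these members 3 were also on the interferon list. The further members Ifi203 (log2 fold change 4.00), Ifi205 (4.23) and Mndal (3.45) carry the GO term for cellular response to interferon-beta. The rise of this list is therefore not independent of the interferon rise. Mavs rose by 0.50, the RNA-editing gene Adar by 1.09, Samhd1 by 0.55 and Sting1 by 0.93 (adjusted p of 0.000112 to 0.000653). The lower member, Rnaseh2c, fell by 0.24 (adjusted p = 0.0339), and 0 members were lower with edgeR without shControl 1, shControl 2, shACSL4 1, shACSL4 2 or shACSL4 3, and with library size alone as scaling. Immune checkpoint ligands and immunosuppressive factors went both ways, with 9 of 21 higher and 4 lower (10 and 4 adjusted over the list alone), a median of 0.34 and camera adjusted p = 0.00926 (adjusted p = 0.292 with an estimated correlation). Beside Cd274, Lgals3 rose 1.53-fold from 165 ± 2.05 to 253 ± 4.49 CPM (adjusted p = 2.25e-06) and Cd47, which encodes a signal against phagocytosis, rose 1.63-fold (adjusted p = 4.34e-06). The lower members were Ptgs2, Lgals1, Pvr and Vegfa. Members outside the naming rule, here and in the lists that follow, were named after their values were seen.

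Chemokines and cytokines had 9 of 22 members higher and 5 lower (9 and 5 adjusted over the list alone), with a median of 0.29. Camera's adjusted p was 0.0467, and adjusted p = 0.292 with an estimated correlation. Cxcl12 rose 3.85-fold, Cx3cl1 2.17-fold and Il15 2.88-fold (adjusted p of 2.03e-05 to 8.56e-05). Cxcl11 had 0 counts in the controls and 94 in shACSL4 (0.71 ± 0.0884 CPM), at least 9.8-fold higher against a floor of 3 counts per library (adjusted p = 0.000132), and the list's median was the same with this bound. Cxcl10, a chemokine that attracts T cells, rose from 14.3 ± 5.36 to 64.9 ± 28.2 CPM (adjusted p = 0.0313). Ccl5 (3.02 against 2.98 CPM, adjusted p = 0.954) and Ccl2 (30.5 against 30.7 CPM, adjusted p = 0.959) did not pass the test. The lower members were Il11, Il23a, Il33, Il34 and Lif. The call of the list ended without shControl 2 (adjusted p = 0.0957), shControl 3 (0.0714), shACSL4 2 (0.0963) or shACSL4 3 (0.0671), with no filter (0.195), with the stricter filter (0.188) and with protein-coding genes alone (0.059), and 3 members were lower without shACSL4 1. The call of Cxcl10 ended without shControl 1 (adjusted p = 0.115), shControl 2 (0.107) or shACSL4 1 (0.0797).

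**Figure D3:**
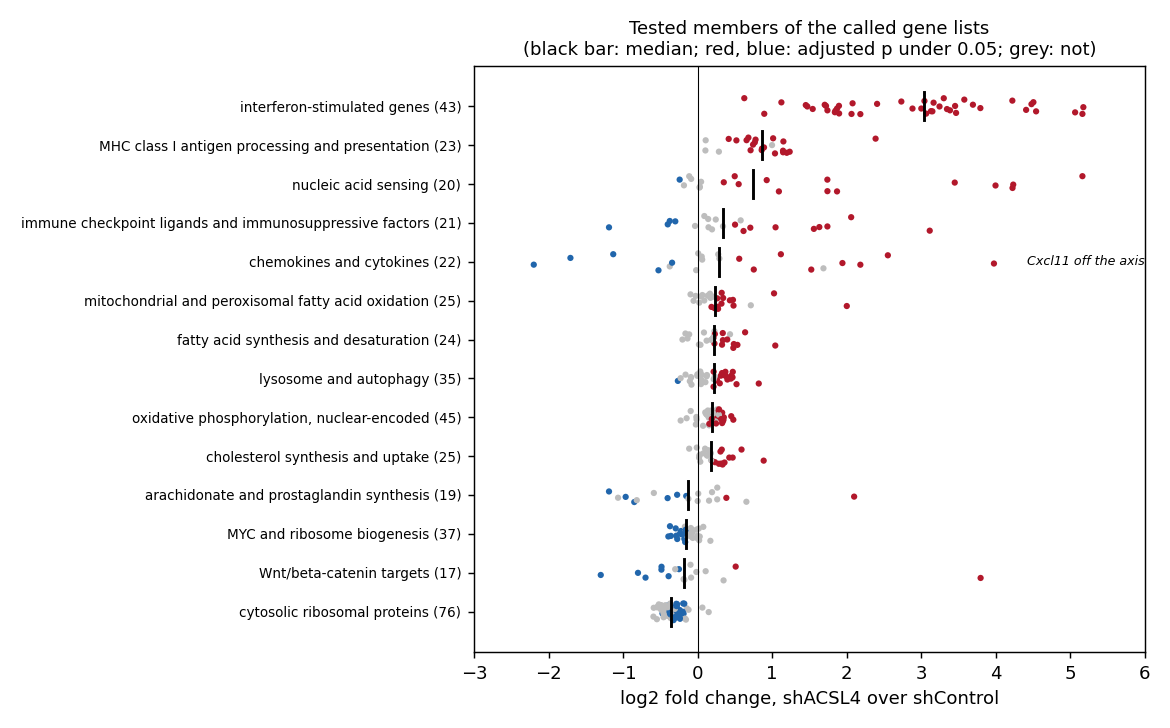
Log2 fold change of shACSL4 over shControl for each tested member of the 14 gene lists that camera called, with the number tested in brackets; points are genes (red higher and blue lower at adjusted p under 0.05, grey not past it) and black bars are medians. Cxcl11, fitted against 0 counts in the controls, lies off the axis. The interferon list has a median of 3.04 with all members above 0, while the medians of the other lists lie between -0.35 and 0.86.

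Among genes of fatty acid activation and uptake, 4 of 14 tested members rose and 3 fell (4 and 4 adjusted over the list alone). Camera gave adjusted p = 0.652, downward, with a median of 0.05 and a mean of -0.14. Acsbg1, another acyl-CoA synthetase gene, fell from 4.89 ± 0.561 to 0.701 ± 0.29 CPM (adjusted p = 6.77e-06), and Acbd3 fell by 0.33 (adjusted p = 0.000646). Acsl5 rose by 0.27 (SE 0.0624, adjusted p = 0.00587), Acsl3 by 0.20 (SE 0.0628, adjusted p = 0.0316) and the transporter gene Slc27a4 by 0.47 (adjusted p = 0.000261), and Fabp4 was the remaining higher member. Acsl1 was at 28.4 and 31.4 CPM (adjusted p = 0.188), and Acsl6 and Acsbg2 had too few counts to test. The call of Acsl3 ended without shControl 1 (adjusted p = 0.125), shControl 2 (0.128), shACSL4 1 (0.1) or shACSL4 2 (0.142).

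Genes of ferroptosis, a cell death driven by peroxidised lipids, moved in both directions. Of 22 tested genes of ferroptosis defence 6 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.892, upward, with a median of -0.04 and a mean of 0.05). Slc7a11, the cystine transporter gene, fell to 24.3 ± 1.07 from 43 ± 2.67 CPM (log2 fold change -0.82, SE 0.0733, adjusted p = 5.55e-06). Nqo1 rose 2.02-fold (adjusted p = 6.1e-06), the ferritin gene Fth1 rose 1.27-fold and Gclc 1.24-fold (adjusted p = 0.000286 and 0.00106). Gpx4, which encodes the peroxidase that detoxifies lipid hydroperoxides, was at 164 ± 27.3 and 157 ± 8.9 CPM (adjusted p = 0.695), and fell by 0.20 without shControl 3 (adjusted p = 0.00689). The other lower members were Slc3a2, the partner of Slc7a11, and Vkorc1l1, and 5 members were lower without shControl 3. Ferroptosis-promoting enzymes and iron uptake had 6 of 18 higher and 3 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.553), or 5 lower without shControl 3. Lpcat3, which inserts polyunsaturated fatty acids into phospholipids, rose 1.33-fold, Steap3 1.41-fold and the transferrin receptor gene Tfrc 1.36-fold, while Slc39a14 fell by 0.41 on the log2 scale (adjusted p of 9.84e-05 to 0.000285). Cyb5r1 and Agps were the other lower members.

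Arachidonate release and prostaglandin synthesis had 2 of 19 members higher and 6 lower (2 and 6 adjusted over the list alone), with a median of -0.12 and camera adjusted p = 0.0391 (adjusted p = 0.292 with an estimated correlation). Ptgs2, the inducible prostaglandin synthase gene, fell from 142 ± 13 to 62.5 ± 1.01 CPM (log2 fold change -1.19, SE 0.0666, adjusted p = 1.15e-07). Ptges, which makes prostaglandin E from its product, fell from 180 ± 14.8 to 99.8 ± 5.6 CPM (adjusted p = 2.25e-06), and the phospholipase gene Pla2g4a fell by 0.40 (adjusted p = 0.00041). The transporter gene Abcc4 rose 1.31-fold (adjusted p = 0.00143), and Ptgds was the other higher member. The list's call ended without shControl 1 (adjusted p = 0.0735), shACSL4 2 (0.0963) or shACSL4 3 (0.0571), and with the replicate number as a block (0.0543).

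Fatty acid synthesis and desaturation had 12 of 24 members higher and 0 lower at adjusted p under 0.05 (13 and 0 adjusted over the list alone), with a median of 0.23 and camera adjusted p = 0.0017 (adjusted p = 0.292 with an estimated correlation). Acss2 rose 1.56-fold, Acaca 1.45-fold, the desaturase gene Scd1 1.4-fold and the transcription factor gene Srebf1 1.32-fold (adjusted p of 2.89e-05 to 0.000166). Cholesterol synthesis and uptake had 12 of 25 higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 0.18 and camera adjusted p = 0.000815 (adjusted p = 0.292 with an estimated correlation). Idi1 rose 1.5-fold and Pmvk 1.34-fold (adjusted p = 5.23e-05 and 0.000345). Fatty acid oxidation had 13 of 25 higher and 0 lower (13 and 0 adjusted over the list alone; 7 higher without shACSL4 1), with a median of 0.23 and camera adjusted p = 0.000789 (adjusted p = 0.503 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, rose 2.04-fold from 33.7 ± 2.12 to 68.6 ± 5.75 CPM (adjusted p = 1.14e-06), and Ppargc1a, a coactivator of mitochondrial genes, rose 4.01-fold to 86.8 ± 9.02 CPM (adjusted p = 3.84e-05). Phospholipid remodelling and triglyceride storage had 5 of 35 higher and 5 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.892, downward, and fry upward). In it Pcyt1a rose 1.4-fold and Lpin1 1.38-fold, while Lpin3 fell to 1.45 ± 0.225 from 5.46 ± 1.25 CPM (adjusted p of 2.51e-05 to 5.74e-05). Lpcat3, Agpat5 and Pnpla2 were also higher, and Lclat1, Gpat3, Hilpda and Cept1 also lower. The number of lower members in this list was 8 without shControl 3 and 3 without shControl 2, shACSL4 1 or shACSL4 2.

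Nuclear-encoded oxidative phosphorylation genes had 18 of 45 members higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 0.19 and camera adjusted p = 0.00108 (adjusted p = 0.688 with an estimated correlation). Cox6a1 rose by 0.48 (SE 0.0493, adjusted p = 1.63e-05) and Sdha by 0.45 (SE 0.0514, adjusted p = 3.84e-05). The list's median over the control mean was 0.0865, 0.0977 and -0.189 in shControl 1 to 3 and 0.255, 0.215 and 0.121 in shACSL4 1 to 3. shControl 3 thus lay apart from the other controls. Whether a difference among libraries that does not follow the shRNA accounts for the rise was not tested for this list. This call ended without shControl 3 (adjusted p = 0.0522, 4 members lower), and 10 members were higher without shACSL4 1. Lysosome and autophagy genes had 17 of 35 higher and 1 lower (18 and 3 adjusted over the list alone; 5 lower without shControl 3), with a median of 0.22 and camera adjusted p = 0.00234 (adjusted p = 0.292 with an estimated correlation). The cathepsin gene Ctsb rose from 771 ± 29.4 to 1051 ± 9.98 CPM (adjusted p = 4.19e-05), and Tfeb, a transcription factor of lysosomal genes, rose 1.77-fold (adjusted p = 0.000126), while the lower member was Becn1. Mitochondrially encoded mRNAs had 0 of 13 members past the threshold with edgeR (0 adjusted over the list alone; camera adjusted p = 0.486), and mt-Co1 was at 12770 ± 2819 and 16710 ± 1315 CPM (adjusted p = 0.121). Without shControl 3 the test of that list gave adjusted p = 0.00559 and mt-Co1 rose by 0.59 (adjusted p = 2.82e-07). Mitochondrial transcripts held 3.98%, 3.79% and 5.85% of counts in shControl 1 to 3 and 4.93%, 6.31% and 5.48% in shACSL4 1 to 3.

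Cytosolic ribosomal protein genes had 36 of 76 members lower and 0 higher (44 and 0 adjusted over the list alone), with a median of -0.35 and camera adjusted p = 3.2e-08 (adjusted p = 0.609 with an estimated correlation). Rpl4 fell by 0.32 from 1766 ± 33.9 to 1416 ± 66.7 CPM (adjusted p = 0.000771), and Rpl6 and Rpl7 fell by the same 0.32 (adjusted p = 0.00144 and 0.00383). These genes held 4.4%, 4.42% and 3.46% of counts in shControl 1 to 3 and 3.38%, 3.37% and 3.08% in shACSL4 1 to 3. The count of lower members was 14, 16 and 69 without shControl 1, 2 and 3, and 19, 29 and 13 without shACSL4 1, 2 and 3. MYC targets and ribosome biogenesis had 16 of 37 lower and 0 higher (20 lower and 1 higher adjusted over the list alone; 9 lower without shACSL4 2 and 8 without shACSL4 3), with a median of -0.15 and camera adjusted p = 0.00275 (adjusted p = 0.459 with an estimated correlation). Odc1, a polyamine synthesis gene, fell by 0.37 (SE 0.0509, adjusted p = 0.000169) and Nop56 by 0.27 (SE 0.0543, adjusted p = 0.00244).

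Targets of Wnt signalling had 7 of 17 members lower and 2 higher (9 and 3 adjusted over the list alone), with a median of -0.19, a mean of -0.03 and camera adjusted p = 0.0477 (adjusted p = 0.536 with an estimated correlation). Ccnd1, which encodes cyclin D1, fell from 424 ± 22.5 to 303 ± 12.3 CPM (adjusted p = 5.74e-05), the Wnt antagonist gene Dkk2 fell by 1.30 (adjusted p = 9.81e-06) and Ephb2 by 0.70 (adjusted p = 0.000234). Lgr5, a stem cell receptor gene, rose from 0.0641 to 0.934 CPM (adjusted p = 0.000111), with control levels near the floor, and Rnf43 was the other higher member. The list's call ended without shControl 2 (adjusted p = 0.0529), shControl 3 (0.13), shACSL4 1 (0.055) or shACSL4 3 (0.101), with DESeq2's size factors (0.0504), with the replicate number as a block (0.0527) and with protein-coding genes alone (0.0642). Of the 14 calls by camera, 0 held with an estimated correlation (smallest adjusted p = 0.292, 2 lists at an unadjusted p under 0.05), while fry, which compares a list with no other genes, called 18 lists. These held 12 of the 14, without cytosolic ribosomal proteins (adjusted p = 0.0917) and oxidative phosphorylation (adjusted p = 0.0929). Outside the 14, fry called fibroblast markers (fry adjusted p = 0.00304), NF-kappaB response (0.00875) and ferroptosis-promoting enzymes (0.0205), all upward. It also called p53 targets (0.00875), G1/S genes (0.0205) and chaperones (0.0357), all downward.

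The lists of stress responses and the cell cycle were not called by camera at the preset correlation, but with no filter on low counts it called ATF4 targets, chaperones and G1/S genes (adjusted p = 0.0307 each) and p53 targets (0.0431). ATF4 targets had 12 of 30 lower and 5 higher (12 and 5 adjusted over the list alone; camera adjusted p = 0.0681, with further calls at 0.00257 without shControl 3 and 0.0371 without shACSL4 1). The amino acid transporter gene Slc7a5 fell by 0.51 and Cth by 1.00, while Atf5 rose by 0.62 (adjusted p of 9e-05 to 0.000931). Slc7a1, Cebpb, Vldlr and Nupr1 were the other higher members. Endoplasmic reticulum chaperones had 9 of 30 lower and 3 higher (11 and 3 adjusted over the list alone; camera adjusted p = 0.0945). The oxidase gene Ero1a fell from 745 ± 86.6 to 436 ± 40.9 CPM (adjusted p = 0.000116) and Calr rose 1.34-fold (adjusted p = 0.000166), with Herpud1 and Derl3 also higher. Targets of p53 had 7 of 26 lower and 2 higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.101), and Cdkn1a, a cell cycle inhibitor gene, fell from 70.6 ± 4.46 to 45.7 ± 3.71 CPM (adjusted p = 4.57e-05). Fas and Sesn1 were the higher members. G1/S genes had 7 of 32 lower and 0 higher (5 and 0 adjusted over the list alone; camera adjusted p = 0.0878), and Ccne2 fell by 0.44 (adjusted p = 0.000842) while Cdt1 fell by 0.35 (adjusted p = 0.00117). G2/M genes had 4 of 34 higher and 1 lower (0 and 1 adjusted over the list alone; camera adjusted p = 0.606), and the lower member, Bub1, fell by 0.27 (adjusted p = 0.00153). The higher ones were Aurka, Bub1b, Cenpf and Foxm1. Left-out libraries moved these counts: lower ATF4 targets were 6 without shControl 2 and 7 without shACSL4 2, and lower chaperones 5 without shControl 2 and 14 without shControl 3. Lower G1/S genes were 4 without shControl 1 and 3 without shControl 2, shACSL4 2 or shACSL4 3, and higher G2/M genes were 0 without shControl 1 or shACSL4 3, 1 without shControl 2 or shACSL4 1, and 15 without shControl 3.

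NF-kappaB response genes had 8 of 23 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.189), and Bcl3 rose 2.59-fold while Ier3 fell by 1.04 (adjusted p = 6.92e-06 and 7.44e-06). Higher members of that list were 4 without shControl 1, shACSL4 1 or shACSL4 2 and 5 without shControl 2 or shACSL4 3. NRF2 targets had 10 of 32 higher and 5 lower (11 and 5 adjusted over the list alone; camera adjusted p = 0.892, upward, with a median of -0.02 and a mean of 0.14), and Abcc1 fell by 0.45 (adjusted p = 6.5e-05), with Slc7a11, Ugdh, Cat and Akr1c13 the other lower members. Hypoxia and glycolysis genes had 6 of 35 higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.892, upward, with a median of 0.04 and a mean of -0.03), or 8 lower without shControl 3. The hexokinase gene Hk1 rose 1.72-fold and Pfkp 1.4-fold (adjusted p = 2.63e-06 and 5.72e-05), while Slc2a1, Ero1a, Ndrg1 and Vegfa were lower. Epithelial-mesenchymal transition and matrix genes had 9 of 33 higher and 11 lower (9 and 12 adjusted over the list alone; camera adjusted p = 0.543). The stromelysin gene Mmp10 fell to 9.95 ± 0.879 from 22.4 ± 1.74 CPM and Vim, the vimentin gene, fell by 0.52, while Twist2 rose 2.03-fold and Col6a2 1.81-fold (adjusted p of 4.34e-06 to 1.58e-05). Replication-dependent histones had 1 of 29 higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.831, downward, with a median of -0.11 and a mean of 0.05); H2ac6 was at 0.241 and 0.645 CPM (adjusted p = 0.0248), and its call ended without shControl 1 (0.0679), shControl 2 (0.0895), shACSL4 2 (0.0624) or shACSL4 3 (0.135) and with DESeq2 (0.0617).

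Among markers of cell types, those of fibroblasts had 3 of 11 higher and 2 lower (3 and 2 adjusted over the list alone). Camera gave adjusted p = 0.353, upward, with a median of -0.01 and a mean of -0.02. Fry called the fibroblast list, upward (fry adjusted p = 0.00304). Pdgfra, a growth factor receptor gene, rose from 122 ± 4.48 to 264 ± 12 CPM (adjusted p = 4.85e-08) and Col3a1 from 867 ± 75.5 to 1178 ± 81.3 CPM (adjusted p = 0.000579). Pdgfrb was the remaining higher member, and Dcn and Postn were lower. Endothelium markers had 1 of 5 higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.925, upward, with a median of -0.39 and a mean of 0.31); the higher member, Erg, was at 0.0483 and 0.804 CPM. Markers of colorectal epithelium, the tissue this line comes from, had only 5 of 20 measured genes with enough counts to test. Of these 5, 1 was higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.892). The higher member, Krt20, was at 0.94 and 1.69 CPM (adjusted p = 0.0361). The call of Krt20 ended without shControl 1 (0.0518), shControl 2 (0.106), shControl 3 (0.0524), shACSL4 1 (0.168) or shACSL4 3 (0.0612) and with DESeq2 (0.0606). The myeloid list and the list of T and NK cells had fewer than 5 tested members and no list test. Lyz2, a lysozyme gene of myeloid cells, rose from 1.57 to 4.66 CPM (adjusted p = 9.26e-05), while Ptprc, which every leukocyte expresses, was at 0.0158 and 0.0618 CPM.

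The authors' deposited comparison marked 736 genes up and 142 down, all with an absolute log2 fold change of at least 1, and held 4011 genes with an adjusted p under 0.05. Across genes, which are not independent replicates, the authors' log2 fold changes correlated with those of edgeR at r = 0.9998. By adjusted p under 0.05 alone, 3831 of the genes tested here passed in both, 3831 of them in the same direction, 324 in edgeR alone and 75 in the authors' table alone. The authors' value for Acsl4 was -0.61 (their adjusted p = 8.89e-22).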

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

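The member counts of lists under other settings and the length-matched comparison were chosen after seeing the data. The fall of Acsl4 kept its direction and call in every setting run, with a log2 fold change between -0.63 and -0.58. Genes changed numbered 4143 with DESeq2's size factors, 4088 with library size alone, 4062 with DESeq2, 4127 with limma-voom, 4528 with no filter, 3915 with the stricter filter and 3924 with protein-coding genes alone. Replicate numbers used as a block gave 5163. Libraries of the same number correlated by 0.0826, 0.0637 and 0.126 after removal of group means, and those of different numbers by -0.116 to 0.0463. The same-number values were the higher ones but weak. Removal of group means ties these values to each other, so they cannot decide whether libraries are paired. No pairing was assumed, because the labels do not say that the number marks a shared day or culture. A factor shared by libraries of the same number stays open. With single libraries left out, changed genes ranged from 2944 to 5477, higher genes from 1666 to 2818 and lower genes from 1252 (without shACSL4 3) to 2659 (without shControl 3). The 5477 were found without shControl 3, the control least like the others. Its counts differed from those of shControl 1 and 2 by a chi-square of 38.67 and 43.2 per degree of freedom. Between shControl 1 and 2 this value was 6.249, and between shACSL4 libraries 12.32 to 21.16. A fold change threshold of 1 on the log2 scale left 839 genes, 706 higher and 133 lower, by its construction. Camera called 14 lists at the preset correlation and 0 with an estimated correlation (2 at an unadjusted p under 0.05), while fry called 18. Other settings called 12 to 17 lists, and left-out libraries 11 to 14. Of 2011 repeats over the 144 named genes, 1965 kept their side of the threshold, 40 lost the call and 6 gained it. Direction was checked only for genes called in the main test, and 0 of their repeats reversed. Among genes not called there, Ccl5 (log2 fold change -0.136 to 0.128), Ccl2 (-0.0676 to 0.0889) and Gpx4 (-0.195 to 0.0096) changed sign between settings. Depth set a floor of 0.0637 to 0.0733 CPM, so folds of genes with control levels near it, such as Lgr5, Erg and Cxcl11, are poorly bounded. The causes were not tested.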

Other observations

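The tests of leukocyte genes, of a single library behind the interferon rise, of short transcripts, of differences among libraries, of the summed protocadherins and of ERK targets were chosen after the result was seen, as were the beta protocadherins and the members named from GO and KEGG terms. The KEGG term for complement and coagulation had 12 of 29 tested genes among the higher ones, where 5.27 were expected (Fisher's exact test, adjusted p = 0.0325), 5 lower and 12 not past the threshold. C1s1 rose from 4.51 to 30.3 CPM (log2 fold change 2.75, edgeR adjusted p = 5.73e-09) and C4b from 0.97 to 15.2 CPM (3.97, adjusted p = 2.66e-06). Other complement genes of the term, such as C2 (adjusted p = 0.226) and C4a (0.784), did not pass. Coagulation and fibrinolysis genes of the term went both ways, with F8 (0.78), Pros1 (0.46) and Plat (0.35) higher and F3 (-0.56) and F13a1 (-1.11) lower. The GO term for retinol metabolic process had 8 of 13 genes higher where 1.97 were expected (adjusted p = 0.0104), and the KEGG term for retinol metabolism 10 of 23 where 4.18 were expected (adjusted p = 0.0414). Aldh1a1, a retinal dehydrogenase gene, rose from 16.4 ± 0.789 to 102 ± 6.11 CPM (2.64, SE 0.0699, adjusted p = 4.69e-10).

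The GO term for the tricarboxylic acid cycle had 14 of 28 genes higher where 4.24 were expected (Fisher's exact test, adjusted p = 0.00155). Ogdh rose by 0.65 and Idh3a by 0.36, while Idh2 was lower at -0.23 (edgeR adjusted p = 2.69e-05, 0.000656 and 0.0193). Among the lower genes, rRNA processing held 52 of 134 where 19 were expected (adjusted p = 1.66e-09) and chaperone-mediated protein folding 13 of 21 (adjusted p = 9.07e-05). Focal adhesion was over-represented among the lower genes too, with 41 of 149 (adjusted p = 0.0104). In all, 30 KEGG and 48 GO terms stood out among the higher genes, and 19 and 29 among the lower ones.

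The interferon-stimulated genes rose in all 3 shACSL4 libraries, by medians of 3, 2.48 and 3.47 on the log2 scale over the control mean. Leukocytes in the culture as the source of these transcripts are argued against. The sum of 13 leukocyte genes was 0.809 ± 0.19 CPM in shACSL4, 0.0226% of the 3586 CPM that the interferon list gained. Lyz2, a gene of myeloid cells, and Itgb2, a leukocyte integrin gene, are not among the 13 and did rise. Itgb2 went from 9.87 to 25.2 CPM (edgeR adjusted p = 7.49e-07), so the argument rests on the 13 genes chosen. A single shACSL4 library is argued against as well, because the lowest median with any library left out was 2.80. The shRNA itself, whatever its target, cannot be told apart from lower Acsl4 as the cause, because the series has 1 shACSL4 arm. The controls carry a hairpin too, so a response particular to this hairpin or its dose stays open. The history of the cell population cannot be told apart from these either. Lower Acsl4 therefore stays open too, with a fall of only 0.61 on the log2 scale behind the rise.

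Cytosolic ribosomal protein genes were lower in shACSL4 with a median of -0.355. Loss of short transcripts is argued against, since 1000 lists of other genes matched on transcript length and expression had a median of -0.0615 (range -0.138 to 0.0102). A difference among libraries that does not follow the shRNA may account for much of it: shControl 3 lay -0.364 from the other controls, about the size of the group difference, and shACSL4 lay only -0.0656 from shControl 3. The effect of the shRNA stays open, since shACSL4 lay -0.489 from shControl 1 and 2.

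The clustered beta protocadherins (chromosome 18, 37427865 to 37657532) are neuronal adhesion genes that lie side by side. Of 21 tested, 19 were higher with edgeR and 0 lower, with a median of 1.38 (16 to 20 higher with single libraries left out). The rises were uneven: log2 fold changes were 1.00 to 5.41 from Pcdhb2 to Pcdhb13, but 0.0614 to 0.859 from Pcdhb14 to Pcdhb22. Of 18 tested alpha and gamma protocadherins, 4 were higher and 0 lower. Pcdhb4 rose from 0.838 to 9.64 CPM (adjusted p = 3.22e-08) and Pcdhb5 from 6.18 to 23.2 CPM (adjusted p = 3.83e-07). A move of reads between these similar genes is argued against by their summed level, which rose 1.9-fold from 94.5 ± 4.42 to 179 ± 7.23 CPM. A regional gain of the chromosome is argued against by the 54 genes within 2 Mb, whose median was -0.0162 (quartiles -0.219 and 0.319). A shared change in the regulation of the cluster is a hypothesis that the tests leave open, and whether it follows lower Acsl4, the shRNA or the history of the cell population was not tested.

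Lower output of ERK signalling in shACSL4 is a hypothesis prompted by the KEGG MAPK term, which held 53 lower genes of 211 where 34.6 were expected (Fisher's exact test, adjusted p = 0.0152). The same term held 38 higher genes, and it was not over-represented among the higher genes. They include the receptor genes Egfr (log2 fold change 1.05), Pdgfra (1.11), Erbb3 (0.55) and Fgfr2 (0.57) and the phosphatase gene Dusp1 (0.76). The term alone therefore gives no direction of signalling. Of 10 genes known to answer ERK, 9 fell (Phlda1, Spry2, Spry4, Dusp4, Dusp6, Ccnd1, Epha2, Etv4 and Etv5) and Epha4 rose by 2.48, with a median of -0.51. Of these, Dusp4, Dusp6 and Epha2 belong to the term and Ccnd1 to the Wnt list, so their falls partly restate what prompted the hypothesis. Of the 6 genes outside the term and the fixed lists, 5 fell and Epha4 rose, with a median of -0.59 (camera p = 0.000793 at the preset and p = 0.0534 at an estimated correlation). Etv5 fell by 0.81 (SE 0.0695, adjusted p = 4.15e-06) and Spry4 by 0.83 (SE 0.0768, adjusted p = 7.06e-06). Lower ERK output in shACSL4 may account for these falls, but it stays a hypothesis, since the genes were picked after the term had been seen and ERK activity itself was not measured. With single libraries left out, 8 or 9 of the 10 fell.

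The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4155 changed genes (2205 higher, 1950 lower) with edgeR, and the highest of the other splits gave 0 for each of these counts (at most 1122 genes at an unadjusted p under 0.05, and 0 changed with limma-voom). As many genes, in each count, were found in 1 of the splits, the real one. For gene lists the real split called 14 with camera, again the most in 1 split, and the highest of the other splits called 13. Of the 14 called lists, 4 had their smallest p in the real split: interferon-stimulated genes, MHC class I, nucleic acid sensing and arachidonate release. For the other 10 lists, ribosomal proteins and oxidative phosphorylation among them, another split gave a smaller p. Every other split has shControl and shACSL4 libraries on each side, so the difference between the groups counts there as spread within a side. Such spread lowers the number of genes called, so a count at or near 0 could be foreseen for these splits. The gene counts therefore cannot decide whether chance gave the real result, and no conclusion is drawn from them. Mixed splits also keep part of the difference between the groups, so the list values do not measure chance alone.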
